A study of Caenorhabditis elegans with 2 samples.

How the data were processed

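Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out, per the labels, on whole late embryos of the C. elegans strain RW12244 at 3.5 hours after egg bleaching. In this strain CRISPR placed a TY1, EGFP and FLAG tag on the endogenous sox-2 gene, and an anti-GFP antibody pulled down the tagged protein. Chromatin was fragmented by sonication, with a stated fragment range of 200 to 800 bp. The series holds 1 group of 2 samples, which the labels number as biological replicates 1 and 2. There is no second condition, and the control that the labels name was not analysed here.

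The deposited files are peak lists on the ce11 build, made by the authors. Per the text list deposited with the samples, each replicate has a ranked list and a thresholded list made from that replicate's alignments and a control, and the series has 2 ranked lists, a thresholded list and a conservative thresholded list made from both replicates. The aligner, the peak caller and their versions are not given in the sources used here. The peak signal in each deposited list is the authors' own value for that peak, on a scale that is not given in the sources used here, and it was used to rank and describe peaks. The deposited ranked lists also hold the −log10 of the irreproducible discovery rate (IDR, a measure of how far repeat rankings of a peak differ), with a highest value of 5. Tested on the files, every thresholded peak is a ranked peak with a −log10 IDR of at least 2, an IDR of at most 0.01. Some ranked peaks past that value are missing from the thresholded lists, and the deposited text list names a further input, not described there, for the thresholded lists alone. In the 2 ranked lists of the series, 4 further columns of signal carry no sample name and were not used. Read counts are not part of these lists, so the depth of each library is unknown, and no value could be corrected for it.

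The thresholded list of the series was the main peak set, and ranked peaks of the same list that did not reach the IDR threshold were the background, since they share the caller and the libraries. Peaks were placed on the NCBI WBcel235 genome sequence, the same assembly as ce11, and on the Ensembl release 115 annotation with 19973 nuclear protein-coding genes. Coordinates are given 1-based on ce11. A summit was promoter-proximal from 1000 bp upstream to 200 bp downstream of an annotated 5′ end of a protein-coding transcript, and other summits went in order to coding exon, untranslated region, intron, non-coding gene or intergenic. A gene was assigned the peak whose summit had it as the nearest protein-coding 5′ end within 2000 bp. Motifs were searched on both strands within 50 bp of the summit and in windows of the same width centred 300 bp to each side. Shares have Wilson 95% intervals, which cover counting error over peaks only. Peaks of the same libraries are not independent replicates, so p-values describe these peak lists and not the spread between embryo cultures.

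Shares in 2 sets of peaks or genes were compared with two-sided Fisher's exact tests, motif shares with each peak's own flank by a two-sided exact McNemar test, the chromosome share by a two-sided exact binomial test, and mean GC content within 100 bp of the summit by a two-sided permutation test with 100000 resamples. The flank share of a motif is the mean over both flanks. For 6-mers, a flank drawn at random per peak was used. Fisher's exact test there ignored the pairing of summit and flank. Families of tests were adjusted by the Benjamini-Hochberg method, over 28 gene lists, over 6 genomic classes and over 2080 merged 6-mers, with a threshold of 0.05. Overlap of replicate peaks meant at least 1 bp, beside 1000 random placements of the replicate 2 peaks on the same chromosomes. Replicate signals were paired where summits of the ranked lists lay within 100 bp, and the interval of the correlation came from 1000 bootstrap resamples of regions. The random background used 100000 positions of the nuclear genome.

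Gene lists, tests and alternatives were fixed before the data were examined. Gene classes were taken by name prefix, such as ceh- for homeobox and hsp- for heat shock genes. Members of those families with other names are not in these lists. The genes named are those of the SOX family, the genes assigned to the 12 conservative-list peaks of highest signal that have one, and of each list up to 4 members with the strongest assigned thresholded peak. Of the 5 strongest peaks with no assigned gene the position is given. Any other gene named was chosen after its values were seen, and this is said where it stands. Alternatives used the conservative list, the stronger part of the peaks, each replicate's own list, other windows, other motifs and other backgrounds. Nuclear peaks alone, and nuclear peaks with no tRNA gene within 500 bp, were added as alternatives after seeing the data, as were each replicate's own list for the motif by rank and for the octamer.

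The scripts were tested on simulated data. CATTGT was planted at 146 of 650 random genome positions, and the motif share then came to 33.2%, while the same positions without planting gave an exact McNemar p of 0.46. The 6-mer test called 2 of 2080 6-mers after the planting and 0 before it. Because these positions were random, the simulation does not cover 6-mer calls that arise where summits and flanks differ in base composition. With 1 enriched list among 28, the list test on 19973 genes called that 1 list. The overlap step found 391 of 600 intervals shared where 390 had been copied. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.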

Results

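SOX-2, a transcription factor of the SOX family with an HMG box DNA-binding domain, was mapped on the chromatin of late C. elegans embryos by ChIP-seq through an EGFP tag on the endogenous gene. The 2 biological replicates of whole embryos formed 1 group, and their pooled thresholded list held 677 peaks, 660 on the nuclear chromosomes and 17 on the mitochondrial genome. Peaks had a median width of 284 bp and a median signal of 104.3. The signal is the authors' value for each peak. The ranked list behind it held 8504 peaks, of which 7731 did not reach the IDR threshold of 0.01 and served as background. The depth of the libraries is unknown, because the lists hold no read counts. The data address where SOX-2 sits in the genome at this stage, and which genes and sequences lie there.

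The replicates marked largely the same regions. Of 571 peaks that passed in replicate 1, 375 (65.7%, 95% interval 61.7 to 69.5) overlapped a replicate 2 peak, against 1.82% for randomly placed peaks. In the other direction 375 of 582 replicate 2 peaks (64.4%) overlapped. Most peaks that passed in 1 replicate alone were still ranked in the other, so that 98.2% of replicate 1 peaks and 97.8% of replicate 2 peaks overlapped a ranked peak of the other library. Those lists are long, at 24418 and 23706 peaks, and random placement of them gave 13.2% and 12.98%, a value added after the data were seen. On the nuclear chromosomes, peaks near tRNA genes, the templates of transfer RNA, made up 22.3% of shared replicate 1 peaks and 10.2% of unshared ones (Fisher's exact adjusted p = 0.0019 over 6 comparisons), while the same difference in replicate 2, 22.4% against 14.6%, did not pass (adjusted p = 0.0814). Signal in the replicates correlated across 651 regions of the pooled list, with a Spearman rho of 0.607 (0.544 to 0.657) and a Pearson r of 0.741 on log2 values. Over the 634 nuclear regions alone these were 0.575 and 0.644. Regions are not independent replicates. The conservative list of 651 peaks overlapped 573 of the 677 pooled peaks (84.6%, 81.7 to 87.2).

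**Figure D1:**
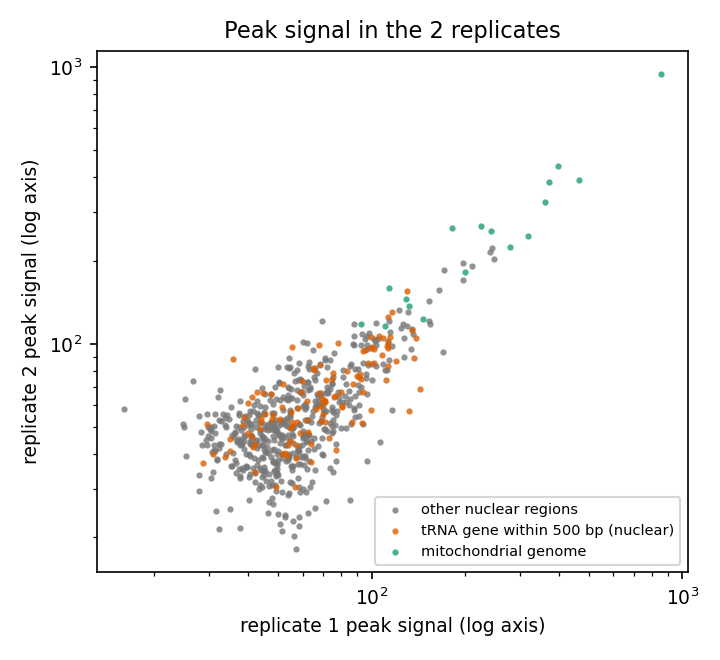
Peak signal in replicate 1 (x axis) and replicate 2 (y axis), both on log axes and in the authors' signal units, for the 651 paired regions of the pooled list. Each point is a region; orange points lie within 500 bp of a nuclear tRNA gene and green points are mitochondrial, which hold the highest signals in both replicates.

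A thresholded peak lay at the promoter of sox-2 itself. A peak at X:7463698-7463981, with its summit at 7463840, just upstream of the most upstream annotated 5′ end of sox-2 at 7463736, had a pooled signal of 133 and a signal of 64.8 ± 3.42 (SD, n = 2) in the replicates, passed in both replicates and in the conservative list, and held the SOX core motif CWTTGT within 50 bp of its summit. A further thresholded peak at X:7455963-7456246, with its summit inside an annotated non-coding gene and 3647 bp downstream of the nearest sox-2 5′ end, had a pooled signal of 89.3. It passed in replicate 1 (51.6) and not in replicate 2 (21.1), and was not in the conservative list. Another thresholded peak at X:7469918-7470201 (signal 148) was promoter-proximal to the neighbouring gene coh-1, which codes for a cohesin subunit and is named here after its values were seen. It passed in replicate 1 (106.2) and not in replicate 2 (44.4), and was in the conservative list. Among the other SOX genes, egl-13, sox-3 and sox-4 had ranked peaks below the threshold only. Their strongest had signals of 66.7, 48.3 and 47.8, with IDR values of 11.2%, 29.7% and 38.8%. No ranked peak was assigned to sem-2. With 1 of 5 members bound, the SOX family did not pass the test (Fisher's exact adjusted p = 0.432).

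**Figure D2:**
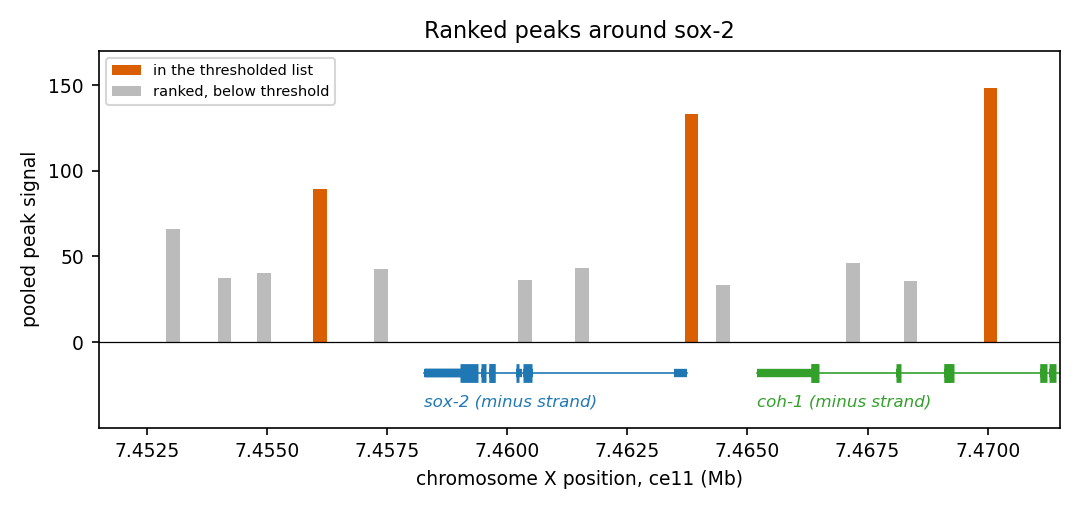
Ranked peaks around sox-2 on chromosome X (ce11, x axis in Mb), with the pooled peak signal on the y axis and bars as wide as the peaks. Orange bars are thresholded peaks and grey bars lie below the threshold; thick boxes below are coding exons, thinner boxes untranslated exons. The peak of signal 133 stands at the most upstream 5′ end of sox-2.

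The strongest nuclear peaks with an assigned gene lay at F55C5.17 (V:12303503-12303753, signal 469), W03C9.1 (II:11960712-11960958, 461), the chemoreceptor genes str-56 (V:15873871-15874097, 406) and sre-23 (I:8259443-8259683, 397), K12H4.5 (363), T02E1.2 (301), C04A11.5 (288), the MAP kinase gene mpk-2 (269), cox-5A (260), which codes for a subunit of cytochrome c oxidase, Y43F8C.7 (259), the ribosomal protein gene rpl-3 (259) and T27A3.8 (253). Of these 12, 1 summit held the SOX core motif, that at F55C5.17, and 1 lay within 500 bp of a tRNA gene, that at C04A11.5. Assignment was by nearest 5′ end alone. Peaks at F55C5.17 (summit 1080 bp downstream of its 5′ end), W03C9.1 (1289), str-56 (1397), C04A11.5 (987) and T27A3.8 (989) lay past the gene's 3′ end. The replicates gave 200.6 ± 13.5 (SD, n = 2) at str-56 and 196.7 ± 1.24 at sre-23. The 5 strongest nuclear peaks without an assigned gene lay in introns at V:8500434-8500691 (438), V:11314090-11314348 (372) and X:9743494-9743777 (246, over a tRNA gene), in a non-coding gene at IV:11026086-11026322 (329) and in intergenic sequence at II:5097534-5097817 (269).

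Genes for ribosomal proteins and histones carried SOX-2 peaks more often than other genes, and chemoreceptor genes less often. Peaks were assigned to 451 of 19973 protein-coding genes (2.26%). Ribosomal protein genes were bound at 9 of 78 (11.5% against 2.22% of other genes, Fisher's exact adjusted p = 0.000906), all 9 at the promoter. Among them rpl-3 had replicate signals of 127.7 ± 7.35 (SD, n = 2), rpl-35 87.2 ± 18.7, rpl-15 80.96 ± 29.7 and rpl-12 81.2 ± 16.4. With replicate 1 alone the ribosomal share fell to 7.69%, close to the threshold (Fisher's exact adjusted p = 0.0499). Histone genes were bound at 7 of 72 (9.72% against 2.23%, Fisher's exact adjusted p = 0.0111), with his-61 at 100.6 ± 18.2, his-32 at 80.3 ± 9.78, his-68 at 61.5 ± 27.3 and his-67 at 56.1 ± 40.8, and 4 of the 7 summits held the SOX core motif. The his-68 peak passed in replicate 2 only, and the his-67 peak in replicate 1 only and not in the conservative list. Not all histone summits lay at promoters. The his-67 summit was intergenic, 1966 bp downstream of the 5′ end and past the gene's 3′ end. A further histone summit was intergenic as well, 1355 bp downstream of the 5′ end. The histone call was lost with either replicate's own list, at 6.94% in each (Fisher's exact adjusted p = 0.0858 with replicate 2 alone and 0.109 with replicate 1 alone). Of 1276 chemoreceptor genes 5 were bound (0.392% against 2.39%, Fisher's exact adjusted p = 1.31e-06), among them srd-43 (104.9 ± 11.9) and sre-13 (62.2 ± 0.0557), both within 500 bp of a tRNA gene. Among genes with any ranked peak, the chemoreceptor share was lower without passing the test (4.55% against 10.2%, Fisher's exact adjusted p = 0.495). No control was analysed. At ribosomal protein and histone genes, signal without specific binding and reads shared between gene copies were not tested as explanations.

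**Figure D3:**
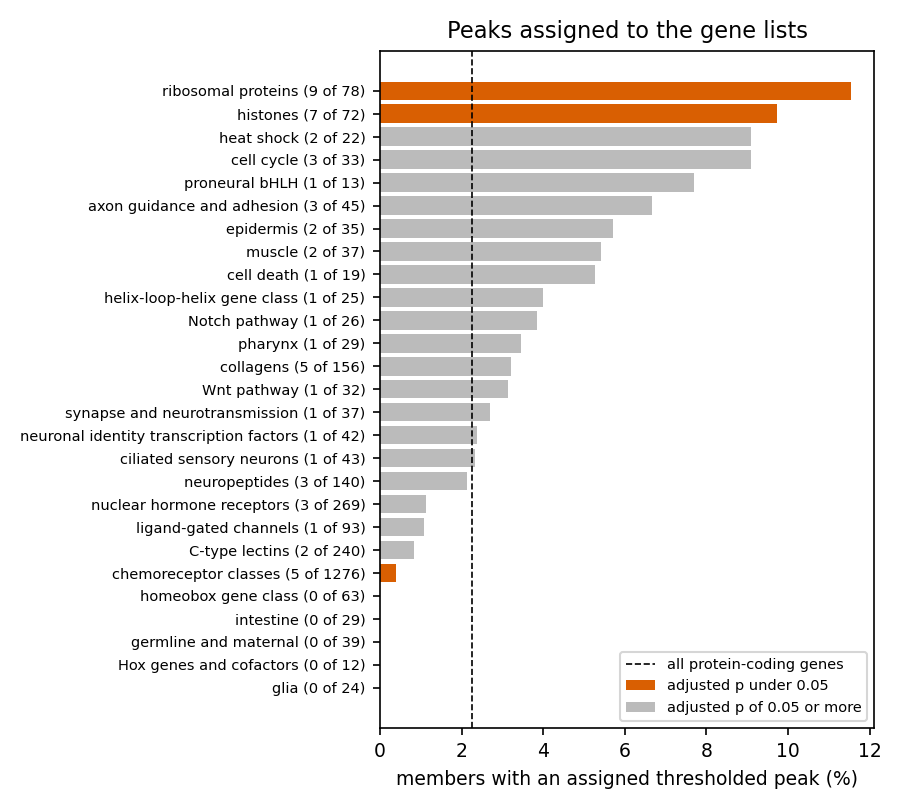
Percent of the members of each gene list with an assigned thresholded peak (x axis), for the lists of at least 12 genes, with bound and total members in brackets. Orange bars passed an adjusted p of 0.05, grey bars did not, and the dashed line marks the 2.26% of all protein-coding genes; ribosomal proteins and histones lie above it and chemoreceptors below.

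Lists of neural and developmental genes did not pass the test, and few of their members had a peak. In the proneural list 1 of 13 genes was bound, hlh-2, the common partner of proneural helix-loop-helix proteins, with a pooled signal of 137 at I:7194928-7195211 and 66.7 ± 10.9 (SD, n = 2) in the replicates; the same gene was the 1 bound member of the helix-loop-helix class (25 genes) and of the cell death list (19). Of 42 neuronal identity factors 1 was bound, egl-46, which codes for a zinc finger protein (37.6 ± 2.59), through a peak of the pooled list that passed in neither replicate alone. The synapse list (37 genes) had syd-2, which codes for liprin-alpha (46.98 ± 13.4), and the ciliated neuron list (43) had daf-19, the RFX factor of ciliogenesis, with 2 promoter-proximal peaks (42.6 ± 18.6 and 41.9 ± 11.1), of which the first passed in replicate 2 only and not in the conservative list, and the other in neither replicate alone. Axon guidance and adhesion genes were bound at 3 of 45, namely the semaphorin gene mab-20 (56.9 ± 13.1), unc-76 (44.03 ± 13.2) and the cadherin gene fmi-1 (38.1 ± 20.4), with a Fisher's exact adjusted p of 0.408. The peak at unc-76 passed in replicate 2 only, and that at fmi-1 in replicate 1 only and not in the conservative list. With assignment up to 5000 bp this list passed (15.6%, Fisher's exact adjusted p = 0.0039). None of 24 glial genes, 63 homeobox genes named ceh-, 12 Hox genes and cofactors, 29 intestinal genes or 39 germline and maternal genes had an assigned peak (0 bound in each). In lists of this length 0 bound does not show depletion.

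In the epidermis list (2 of 35) the peaks lay in introns by the neighbouring GATA factor genes elt-6 (IV:1916441-1916511, signal 201.4, 101.2 ± 2.66 in the replicates) and egl-18 (IV:1903801-1904084, signal 61.8, 29.8 ± 11.5 in the replicates). The egl-18 peak passed in replicate 1 only and was not in the conservative list. The muscle list (2 of 37) had pat-4, which codes for integrin-linked kinase (54.2 ± 8.28), and the actin gene act-4 (40.1 ± 7.58). The Notch effector lag-1 was the 1 bound gene of both the Notch (26) and pharynx (29) lists, with a peak in an intron at IV:6097175-6097458 (56.6 ± 8.51) that held the SOX core motif. The Wnt list (1 of 32) had the receptor gene cam-1 (40.3 ± 8.96). The peaks at act-4 and cam-1 passed in replicate 1 only. Cell cycle genes were bound at 3 of 33 (9.09%, Fisher's exact adjusted p = 0.265), the cyclin E gene cye-1 (106.6 ± 8.72, over a tRNA gene), cdk-4 (47.3 ± 4.85) and cdc-14 (41.6 ± 4.04). The cdc-14 peak passed in replicate 2 only. With replicate 2 alone the cell cycle list passed (12.1%, Fisher's exact adjusted p = 0.0325). Heat shock genes were bound at 2 of 22, hsp-1 (84.0 ± 1.35) and hsp-3 (41.6 ± 10.8), with a Fisher's exact adjusted p of 0.408. With all genes within 2000 bp of a summit assigned, this list passed (22.7%, Fisher's exact adjusted p = 0.00623).

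Of the large gene classes, 5 of 156 collagen genes were bound, and at 3 of them the summit lay within 500 bp of a tRNA gene. The strongest were col-94 (122.2 ± 5.52), col-181 (123.2 ± 9.32), col-85 (107.1 ± 2.45) and col-185 (72.9 ± 1.86). Nuclear hormone receptor genes were bound at 3 of 269, nhr-255 (99.0 ± 4.38), nhr-48 (52.7 ± 0.635) and nhr-41 (46.6 ± 11.2), neuropeptide genes at 3 of 140, nlp-76 (105.0 ± 9.75), ins-13 (64.2 ± 15.9) and flp-23 (55.3 ± 5.29), and C-type lectin genes at 2 of 240, clec-266 (67.8 ± 7.34) and clec-140 (46.3 ± 5.38). Ligand-gated channel genes were bound at 1 of 93, lgc-44, whose peak had a signal of 62.3 in replicate 1 and no ranked summit within 100 bp in replicate 2. The summits at nhr-255, nhr-41, nlp-76 and flp-23 lay within 500 bp of a tRNA gene. The peaks at nhr-41 and clec-140 passed in replicate 2 only, and the lgc-44 peak was not in the conservative list. None of these 5 classes passed the test, with Fisher's exact adjusted p-values of 0.738 for collagens, 0.692 for hormone receptors, 1 for neuropeptides, 0.569 for lectins and 0.884 for channels.

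The SOX core motif was enriched at summits. CWTTGT lay within 50 bp of 135 of 676 summits (19.97%, 95% interval 17.1 to 23.2) and in 10.8% of the flanks (exact McNemar p = 8.57e-06). Of the 2 sequences it covers, CATTGT accounted for the rise, at 14.9% of summits against 5.77% of flank windows (Fisher's exact adjusted p = 6.11e-07), while CTTTGT stood at 5.77% against 5.62% (adjusted p = 1). Peaks below the threshold also held CWTTGT above their flanks, at 16.5% against 10.2%, and less often than thresholded peaks (Fisher's exact adjusted p = 0.0404 over 5 comparisons). Signal did not order the motif: it lay at 18.3% of the 338 stronger and 21.5% of the 339 weaker thresholded summits (Fisher's exact adjusted p = 0.42). The shorter core WTTGT was not enriched (52.96% of summits, 58.1% of flanks, exact McNemar p = 0.236). The octamer ATGCWAAT, recognised by POU proteins that partner SOX factors, lay at 14 of 676 summits (2.07%, 1.24 to 3.45) and in 1.26% of flanks (exact McNemar p = 0.286).

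Nuclear peaks near tRNA genes and other nuclear peaks differed in the motif. Away from tRNA genes 130 of 542 summits held CWTTGT (24.0%, 20.6 to 27.8, flanks 11.1%, exact McNemar p = 1.42e-08). Within 500 bp of a tRNA gene 3 of 118 did (2.54%, 0.868 to 7.21, flanks 10.6%, exact McNemar p = 0.146), and the 2 shares differed (Fisher's exact adjusted p = 9.38e-09). Of tRNA genes with no peak nearby, 1.47% held the motif within 50 bp of their middle.

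**Figure D4:**
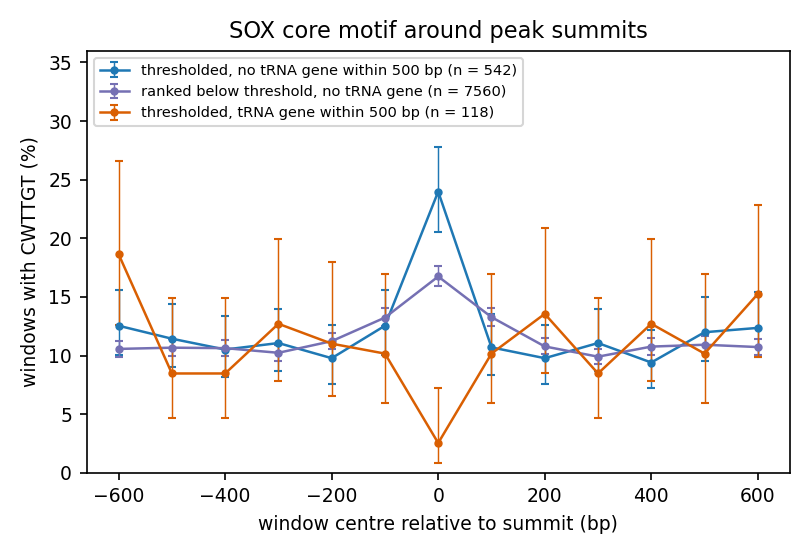
Percent of windows with CWTTGT (y axis) in windows reaching 50 bp to each side of a point at the distance from the summit on the x axis (bp), for nuclear peaks. Points are shares and bars their Wilson 95% intervals; thresholded peaks away from tRNA genes (blue) reach 24.0% at the summit, ranked peaks below the threshold (purple) 16.7%, and peaks near tRNA genes (orange) 2.54%.

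Many SOX-2 peaks lay at tRNA genes. Of 677 thresholded summits 130 (19.2%, 16.4 to 22.3) lay within 500 bp of a tRNA gene, against 2.20% of ranked peaks below the threshold (Fisher's exact p = 1.58e-65) and 0.561% of random positions. On the nuclear chromosomes this was 118 of 660 summits (17.9%), and 135 of 612 nuclear tRNA genes (22.1%) had a summit within 500 bp. Much of a tRNA gene recurs elsewhere in the genome: on average 91.1% of the 36-mers in the bodies of tRNA genes with a peak, and 84.7% in the others, occurred more than once. Within 100 bp of the summit, which reaches past the gene body, the share was 27.2% for nuclear peaks near tRNA genes and 6.08% for other nuclear peaks. How reads that map to several copies were placed is not given in the sources used here.

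**Figure D5:**
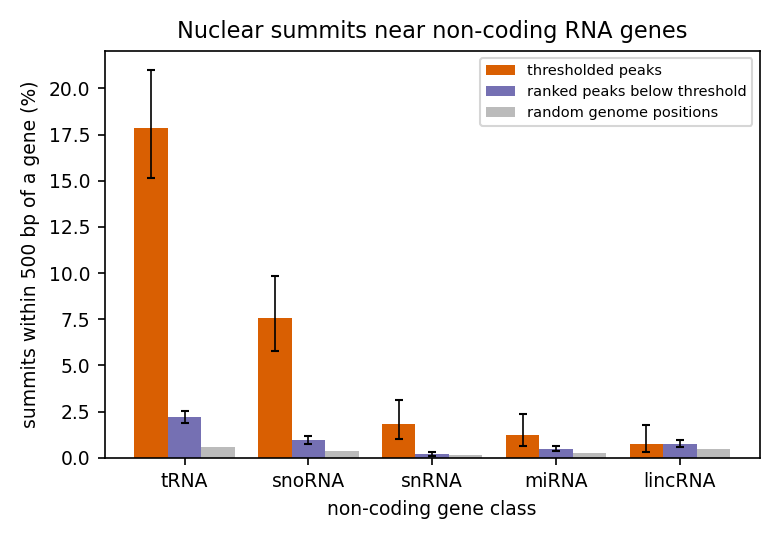
Percent of nuclear summits within 500 bp of a tRNA, snoRNA, snRNA, miRNA or lincRNA gene (y axis) for thresholded peaks (orange), ranked peaks below the threshold (purple) and random genome positions (grey), with Wilson 95% intervals as error bars on the peak shares. Of the classes drawn tRNA genes stand highest, at 17.9% of thresholded nuclear peaks and 2.20% of those below the threshold. The general ncRNA class, at 30.76% and 14.02%, is not drawn.

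Chromosome X carried more peaks than its length would give, and the excess lay at tRNA genes. It held 174 of 660 nuclear peaks (26.4%, 23.1 to 29.9) and 17.7% of the nuclear genome (exact binomial p = 2.96e-08). Chromosome X also holds 276 of the 612 nuclear tRNA genes (45.1%). Of the 118 nuclear peaks near tRNA genes 67 were on X (56.8%), and of the 542 others 107 (19.7%), which did not differ from the genome share (exact binomial p = 0.215). Chromosome III held 117 peaks (17.7%) on 13.7% of the genome with 10.5% of the tRNA genes, and chromosome V 85 peaks (12.9%) on 20.9% of the genome; neither was tested.

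Peaks lay at promoters and rarely in exons. Promoter-proximal summits numbered 309 of 677 (45.6%, 41.9 to 49.4), against 34.7% of peaks below the threshold and 26.3% of random positions (Fisher's exact adjusted p = 3.62e-08). Coding exons held 1.18% of thresholded summits against 12.03% (Fisher's exact adjusted p = 7.97e-25), untranslated regions 0.148% against 3.00% (adjusted p = 1.72e-07) and non-coding genes 7.53% against 2.42% (adjusted p = 1.45e-10). Away from tRNA genes the non-coding gene share did not pass the test (2.95% against 2.13%, Fisher's exact adjusted p = 0.265). Introns (22.9% against 23.7%, Fisher's exact adjusted p = 0.638) and intergenic sequence (22.6% against 24.2%, adjusted p = 0.448) did not differ. These class shares include mitochondrial summits, some of them promoter-proximal or in coding exons, while the random positions were nuclear. With nuclear peaks only, each class kept its direction and its side of the threshold. On the mitochondrial genome, 17 peaks covered 4652 of 13794 bp, with a median signal of 506 against 103 for nuclear peaks, and 9 of the 10 strongest peaks of the list were mitochondrial. Signal was not corrected here for depth or for the amount of mitochondrial DNA, and no control was analysed. Whether SOX-2 binds the mitochondrial genome was therefore not tested.

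Sequence at the summits was richer in G and C than at peaks below the threshold. Mean GC content within 100 bp of the summit was 45.4 ± 7.27% (SD over 677 peaks) against 40.8 ± 7.38% over 7731 peaks below the threshold (permutation p = 1e-05, the smallest the resamples can give). Against their own flanks, 453 of 2080 6-mers were higher at thresholded summits and 299 lower. Those that rose held 4.10 G or C bases on average and those that fell 1.44. GCGCAC rose from 1.18% of flank windows to 12.4% of summits, ACGCAG from 2.22% to 14.2% and AGAGAG from 5.92% to 20.4%, and AAAATT fell from 43.6% to 10.8%. A further background was the 677 peaks of highest signal that failed the IDR threshold. Their signals reached down to 58.9, and those of thresholded peaks to 39.4. Against this background 4 6-mers were higher, among them GTTCGA (14.03% against 5.76%, Fisher's exact adjusted p = 0.000826), while CATTGT was not (14.9% against 12.4%, Fisher's exact adjusted p = 0.895). Peaks near tRNA genes were kept here, at 19.2% of thresholded summits and 2.20% of all peaks below the threshold. The comparison therefore cannot tell these 6-mers from the sequence of tRNA genes.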

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

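The test of the motif described here was chosen after the result was seen. In data that the comparisons above do not use, 96 ranked peaks of the pooled list passed the IDR threshold and were missing from the thresholded list. They have a median signal of 157 and a highest signal of 2123, above the 469 of the strongest nuclear thresholded peak, and 9 of the 10 strongest nuclear ranked peaks are among them. Of the 96, 90 (93.8%) are intergenic. No control sample was analysed here.

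Few of these 96 peaks held the SOX core motif: CWTTGT lay at 4.17% of their summits against 20.2% of nuclear thresholded summits (Fisher's exact p = 2.87e-05). The share in their own flanks was 7.81% (exact McNemar p = 0.453). Repeated sequence may itself fix the motif share, and several of the peaks are close neighbours. The comparison therefore does not decide whether SOX-2 binds there. Sequence repeated in the genome fits the 96 peaks: on average 87.8 ± 16.4% (SD) of the 36-mers at their summits occur more than once, against 9.86 ± 18.6% at the 660 nuclear thresholded summits (permutation p = 9.9999e-06, the smallest the resamples can give). Signal from reads of several copies piled on 1 place is therefore a candidate explanation, and the further input that the authors used for the thresholded lists may have removed such regions. Binding to repeats that does not need the motif stays open.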

How the results depend on the processing

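Settings with nuclear peaks only or without peaks near tRNA genes, and each replicate's own list for the motif by rank and the octamer, were chosen after the data were seen. Of 84 alternative values of the main results, 72 kept their direction and their side of the threshold or their size. Leaving out peaks near tRNA genes ended the excess on chromosome X (19.7%, exact binomial p = 0.215), which follows from the 67 peaks it removes there. Overlap of replicates went from 65.7% to 60.4% with 50% of each interval shared, to 61.2% for nuclear peaks away from tRNA genes, which leaves out mitochondrial peaks too, and to 71.6% among the stronger peaks of each list. Signal correlation was 0.539 over all ranked regions, 0.67 over conservative regions and 0.933 as Pearson r on unlogged values. Without the mitochondrial regions the unlogged r was 0.795; the cause of the other shifts was not tested. The motif test turned with WTTGT (52.96%), and the difference between stronger and weaker peaks, not past the threshold in any setting, turned from -3.19 points to between 1.12 and 2.75 points with each replicate's own list. 6-mers higher at summits fell to 235 among the stronger peaks, where fewer peaks enter the test. They fell to 4 against the peaks of highest signal below the IDR threshold, and the cause was not tested. No value of the overlap or correlation can be had with 1 replicate.

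Calls were kept for ribosomal proteins in 10 of 10 alternatives, for chemoreceptors in 8 and for histones in 7. Beside the losses given above, chemoreceptors did not pass among the stronger peaks (0.392% against 1.14%, Fisher's exact adjusted p = 0.0737), nor histones with 1000 bp (6.94%, Fisher's exact adjusted p = 0.064). Axon guidance and adhesion passed at 5000 bp (15.6%), heat shock with all genes within 2000 bp (22.7%) and the cell cycle with replicate 2 alone. Some lists that passed in no setting turned direction, and the cause was not tested. Values were 0% bound in the stronger peaks for neuronal identity, synapse, ciliated neuron, muscle and Wnt genes, with neuropeptides at 2.14%. With 1000 bp they were 0% for neuronal identity, proneural, epidermis, pharynx, Notch, Wnt, helix-loop-helix and cell death genes. With 5000 bp they were 2.38% for neuronal identity, 4.17% for glia and 2.33% for ciliated neurons. With all genes within 2000 bp they were 2.70% for synapse, 3.45% for pharynx, 5.13% for germline, 3.21% for collagens and 3.57% for neuropeptides. Among genes with a ranked peak they were 5.26%, 6.25%, 8.33%, 6.25% and 12.5% for neuronal identity, synapse, ciliated neurons, Wnt and neuropeptides. Matched random lists turned neuronal identity (2.38%), and peaks away from tRNA genes turned collagens (1.28%). Single replicates gave 0% for neuronal identity in both, for Wnt with replicate 2 alone and for ciliated neurons with replicate 1 alone, and 2.14% for neuropeptides in both. Introns turned among the stronger peaks (25.15%) and intergenic sequence without replicate 2 (23.8%) and away from tRNA genes (26.2%), while without replicate 1 it stayed at 21.5%. The excess in non-coding genes was lost away from tRNA genes (2.95%). Of 53 named genes with a peak, 49 had one in the conservative list, 46 in replicate 2 alone, 44 in replicate 1 alone, 38 among the stronger peaks and 34 with 1000 bp. Among the genes of the 12 strongest assigned peaks, those left without one at 1000 bp were F55C5.17, W03C9.1 and str-56. Depth is unknown, so what it limits cannot be stated.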

Other observations

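The tests of non-coding gene classes and of CATTGT alone, and the choice of genes in the next paragraph, came after the results were seen. Genes for other small structural RNAs also had SOX-2 peaks nearby. Within 500 bp of a snoRNA gene, which codes for a guide of rRNA modification, lay 50 of 660 nuclear summits (7.58%, 95% interval 5.79 to 9.85), against 0.957% of nuclear peaks below the threshold (Fisher's exact adjusted p = 1.9e-23 over 9 classes), and 52 of 346 snoRNA genes (15.03%) had a summit that near. For snRNA genes, which code for splicing RNAs, the shares were 1.82% and 0.181% (Fisher's exact adjusted p = 3.95e-07), and for miRNA genes 1.21% and 0.479% (adjusted p = 0.0405). Without the peaks near tRNA genes, snoRNA genes stood at 9.23% against 0.979% (Fisher's exact adjusted p = 2.89e-26). Genes of the general ncRNA class stood at 30.76% against 14.02% (Fisher's exact adjusted p = 7.45e-25). lincRNA genes (0.758% against 0.763%) and piRNA genes (3.33% against 3.08%) did not differ. For snoRNA and snRNA genes, technical explanations were not tested.

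Peaks that held the SOX core motif, lay away from tRNA genes, passed in both replicates and had an assigned gene numbered 43, at 43 genes, 10 of them members of a gene list. After the peak at F55C5.17, the strongest lay at F44E5.4, a gene of the HSP70 family (signal 247, promoter-proximal), Y40A1A.3 (203), his-61 (203), the autophagy gene epg-9 (192), snr-4, which codes for a core protein of the spliceosome (175), and ints-8, which codes for a subunit of the Integrator complex (171). F44E5.4 is not in the heat shock list, which holds hsp- names only.

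The excess of peaks at tRNA genes was weighed against technical explanations. If signal at highly transcribed loci without specific binding produced it, these summits should lack the SOX motif, and they did (2.54% against 24.0%, Fisher's exact p = 1.88e-09). That cannot be told apart from the sequence of tRNA genes as such, since tRNA genes with no peak also lack it (1.47% of 477). Reads shared between gene copies may contribute: repeated 36-mers made up 91.1 ± 24.2% (SD) of the 135 tRNA genes with a peak and 84.7 ± 30.9% of the 477 others (permutation p = 0.0252), a small difference on a share that is high in both. Within 100 bp of the summits near tRNA genes the share was 27.2 ± 8.16% (SD). At the 96 peaks missing from the thresholded list it was 87.8 ± 16.4%. Recruitment of SOX-2 to tRNA genes stays open and was not tested.

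For the motif excess, the base composition of summits was tested with 6-mers of the same composition. For the weaker of the pair CATTGT and CTTTGT, 81.1% of 148 such 6-mers rose less, so that the 0.148 point rise of CTTTGT could come from composition. This was the test fixed in advance, and by its rule composition stays a possible explanation of the motif excess. For CATTGT, which rose by 9.17 points, 100% of the 6-mers compared rose less. Their median change was -1.48 points, but their largest rise was 8.28 points, close to that of CATTGT. That CATTGT rose most argues against composition alone for this sequence, by a narrow margin and in a test chosen after the results were seen. Binding of SOX-2 to CATTGT is a hypothesis that stays open. The peaks of highest signal below the IDR threshold held CATTGT at 12.4% of summits.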
